A study of Homo sapiens with 17 samples.

How the data were processed

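RNA from 17 samples of the human lung adenocarcinoma lines A549 and H2122 was measured on Affymetrix arrays, 1 array per sample, from 130 ng of total RNA, per the labels' protocols. Cells were grown in 5% serum. The deposited values are log2 expression levels per transcript cluster, made by the authors with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes; RMA subtracts background, makes the arrays' distributions alike and summarises probes. Because it forces like distributions, a shift of most genes in one direction cannot be seen in these values. No detection calls were used, so levels near the lower end cannot be told from background. The genome build is not given in the sources used here, and no coordinates are reported.

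The table held 33297 probe sets. Of these 19181 had 1 gene symbol in the platform annotation, 2055 had several and 12061 were not listed there and are unnamed here, not without a gene. Symbols were updated through the gene identifier against a RefSeq table; 19143 identifiers matched and 0 symbols changed. For the 895 genes with several probe sets the one with the highest mean over all arrays was kept, which left 17958 genes.

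Groups came from the sample titles, which name the line, the construct and the replicate. For 3 H2122 samples the source name gives another construct than the title. The titles were kept, and grouping by source name, and leaving these samples out, were tried as alternatives. No array was moved to another group because of its values. Replicates of a group differed by an SD of 0.226 to 0.608 across genes and were counted separately. Pairs of LKB1 arrays lay between 0.226 and 0.326. The highest values were 0.608 and 0.541 for pairs with A549 K78I replicate 2, and 0.52 for the H2122 pBABE arrays.

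The tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes over 6 groups and Benjamini-Hochberg adjustment over 17958 genes, and a threshold of 0.05. The residual degrees of freedom were 11 and the prior added 3.8. LKB1 was compared with the mean of its 2 control groups, with equal weight, and with each control; the mean over lines and the difference between lines were further contrasts. All groups share 1 estimate of spread per gene, so a gene that is erratic in one line loses power in the other. STK11 also had an exact two-sided permutation test within each line. Gene lists, 30 in number, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, and, as alternatives, with camera at an estimated correlation and with fry's directional test. The list of tumour LKB1-loss score genes was written from memory. Adjusted p-values of lists cover the 30 lists of a comparison.

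The named genes were STK11; for each line and for the mean of both lines, the 8 genes that rose most and the 8 that fell most among called genes whose every LKB1 array lay beyond every control array; up to 4 called members of each list with the lowest adjusted p; and the 5 highest and 5 lowest called differences between lines and between K78I and pBABE. Members of a list that did not pass may be named with their values. Only part of the genes the rule allows are named.

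The fit was tested on simulated data for the A549 comparison of LKB1 with controls, with the real genes' means and spread over 17958 genes. Of 67 genes shifted by 0.5 log2 units 38.8% were called, of 67 shifted by 1 unit 83.6%, and of 66 shifted by 2 units 95.5%. Of 151 calls 3.97% were false. With no shifts 0 genes were called. A list shifted by 0.5 was called by camera and 0 others were. The simulated genes were independent and had the same spread in every group, so this says nothing about lists of correlated genes. For the same reason the share of false calls, and the 0 calls without shifts, need not hold on the real arrays. There another split of the A549 arrays called 2110 genes.

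The alternatives set in advance were a replicate block, grouping by source name, leaving out the samples with conflicting labels, leaving out each array in turn, a filter on the dimmest 30% of genes, median centring, quantile normalization of the tested genes, the mean of a gene's probe sets, a trended robust prior, array weights, a fit per line, pooled controls, and a test of every probe set. The alternatives that leave out arrays at odds with their STK11 label or with low cell cycle genes were added after the data had been seen. Figures were drawn with matplotlib.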

Results

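Gene expression was measured on 17 arrays from 2 human lung adenocarcinoma cell lines, A549 and H2122, both of which lack functional LKB1, the serine/threonine kinase and tumour suppressor encoded by STK11. Each line had been stably infected with a pBABE retrovirus carrying wild-type LKB1, the kinase-dead LKB1 mutant K78I, or no insert, and selected in 1 µg/mL puromycin for 2 weeks. Every group held 3 arrays except H2122 with empty pBABE, which held 2. The study set out to compare the expression differences measured with LKB1 in culture with those that accompany LKB1 loss in resected tumours; the tumour data were not analysed here. The arrays had closely similar distributions, with median levels between 5.62 and 5.73 on the log2 scale. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these arrays, and the number of arrays limits the precision.

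STK11 itself (transcript cluster 8024204) separated the H2122 groups cleanly. Its mean log2 level was 6.28 ± 0.08 with pBABE (SD, n = 2), 11.27 ± 0.08 with LKB1 (n = 3) and 11.28 ± 0.03 with K78I (n = 3), and the wild-type and kinase-dead groups differed by less than the spread between replicates. In A549 the level was 9.76 ± 0.42 with LKB1 (SD, n = 3), but 2 control arrays went against their labels. The array labelled pBABE replicate 3 stood at 10.52, beside 6.88 and 7.38 on the other pBABE arrays. The array labelled K78I replicate 2 stood at 7.14, beside 10.54 and 10.42 on the other K78I arrays. Every direction drawn below from the A549 controls includes these 2 arrays under their labels. STK11 differed between LKB1 arrays and all controls by 0.95 in A549 (exact two-sided permutation p = 0.464, smallest possible 0.0119). It differed by 1.99 in H2122 (exact two-sided permutation p = 0.339, smallest possible 0.0179). The K78I controls carry the transcript too. With limma the LKB1 effect on STK11 was 0.95 ± 0.73 (SE, adjusted p = 0.516) in A549 and 2.49 ± 0.76 (SE, adjusted p = 0.0634) in H2122, where leaving out A549 pBABE replicate 1, K78I replicate 2 or pBABE replicate 3 gave adjusted p = 0.0481, 0.0109 and 0.0146. Against pBABE alone it was 4.99 ± 0.94 in H2122 (SE, adjusted p = 0.00479). The H2122 groups follow the sample titles, and for 3 H2122 arrays the source name gives another construct. The array titled pBABE replicate 2, with LKB1 as source name, stood at 6.22, beside 6.33 on the other pBABE array. The array titled K78I replicate 3, with pBABE as source name, stood at 11.26, so STK11 on these arrays goes with the title. For LKB1 replicate 3, with K78I as source name, the level of 11.26 cannot decide, since LKB1 and K78I arrays had the same level. Its mean of the mesenchymal list lay at 0.424 against the line mean. The other LKB1 arrays lay at 0.478 and 0.389, the K78I arrays at −0.0138, −0.193 and −0.318. For the antigen presentation list it lay at 0.261, the other LKB1 arrays at 0.307 and 0.2, the K78I arrays at −0.0363, −0.129 and −0.156. These values argue against K78I cells on this array. Both lists were called with the array counted as LKB1.

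**Figure D1:**
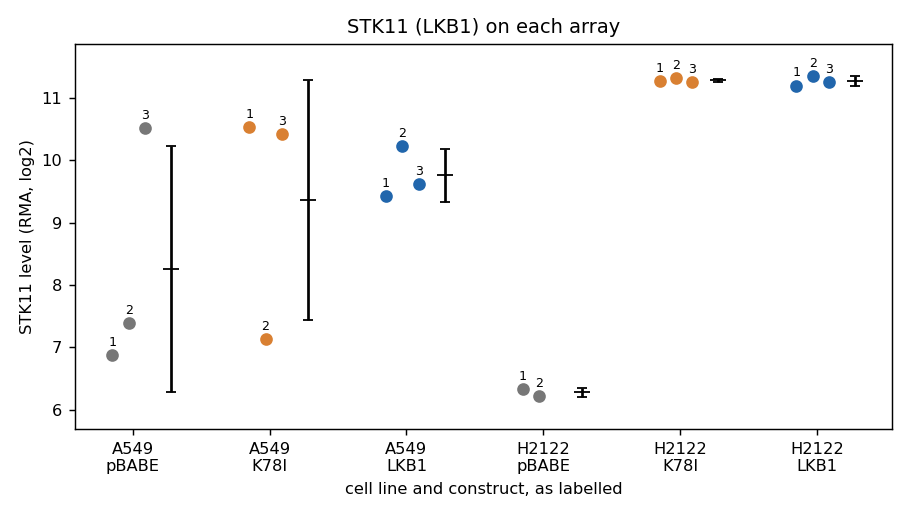
STK11 level (RMA, log2) on each array by cell line and labelled construct, with the replicate number beside each point and the group mean and SD as bars. The array labelled A549 pBABE replicate 3 lies at 10.52 and the array labelled A549 K78I replicate 2 at 7.14, each apart from the rest of its group.

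In A549, SPARC, a secreted matrix glycoprotein, rose from 4.18 ± 0.27 on 6 control arrays to 10.33 ± 0.51 on the 3 LKB1 arrays (SD), a difference of 6.15 ± 0.19 (SE, adjusted p = 7.35e-11). The other large rises were MDGA1 (4.69), the collagen-binding integrin subunit ITGA11 (4.11), the type I collagen chain COL1A1 (3.90), IGFBP7 (3.86), CCDC80 (3.66), SPOCK1 (3.43) and NIPAL4 (3.33). CPS1, the first enzyme of the urea cycle, fell from 10.69 ± 0.78 to 5.33 ± 0.53 (SD), by 5.37 ± 0.46 (SE, adjusted p = 4.6e-06). It was followed by neurotensin (NTS, −5.11), the disulfide isomerase AGR2 (−5.04), GABRA2 (−4.11), the protease inhibitor SLPI (−4.02), the fibrinogen chain FGA (−3.85), INSL4 (−3.71) and the mucin MUC5B (−3.70). These 16 genes were chosen among called genes with every LKB1 array beyond every control array of the line, so that trait was fixed by the choice. Across 17958 genes, limma called 1515 at an adjusted p under 0.05, 985 higher and 530 lower, of which 338 and 180 changed at least 2-fold; after each array was centred on its median, 774 were higher and 718 lower. The count was 844 without LKB1 replicate 1, 715 without LKB1 replicate 3 and 875 when A549 was fitted alone, and the adjusted p of MUC5B was 0.0762, 0.0652 and 0.08 without LKB1 replicates 1, 2 and 3.

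Gene lists were then tested in A549. Of 28 measured targets of CREB and its CRTC coactivators, 10 fell and 0 rose, with a median difference of −0.96 (camera adjusted p = 3.18e-10; adjusted p = 0.279 with an estimated correlation); adjusted over the list alone 13 fell. They included PDE4B (−2.22 ± 0.14, SE) and PDE4D (−0.97), which hydrolyse cyclic AMP, INSL4, and AVPI1 (−2.30). Of 26 mucinous, gastrointestinal and hepatic lineage genes, 12 fell and 0 rose, among them CPS1, AGR2, FGA and vitronectin (VTN, −2.84), with a median of −0.84 (camera adjusted p = 1.54e-07; adjusted p = 0.204 with an estimated correlation) and 13 lower adjusted over the list alone. A list of 14 genes recalled from memory as a tumour score of LKB1 loss had 7 lower and 0 higher, median −1.23 (camera adjusted p = 1.14e-09; adjusted p = 0.204 with an estimated correlation), and 11 lower adjusted over the list alone. As written, it shares AVPI1, PDE4D, IRS2 and SIK1 with the first list and CPS1, FGA, HAL, MUC5AC and TFF1 with the second. It is therefore not independent evidence, and it was not checked against a source. The 3 arrays with the lowest mean of the cell cycle list were all controls, A549 K78I replicate 2 (−0.98 against the line mean), A549 pBABE replicate 1 (−0.40) and H2122 pBABE replicate 2 (−1.38). The first 2 also had the highest CREB and CRTC target means of A549, at 1.67 and 1.09 above the line mean; without the 3 arrays the median of that list was −0.42, with 14 genes lower.

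**Figure D2:**
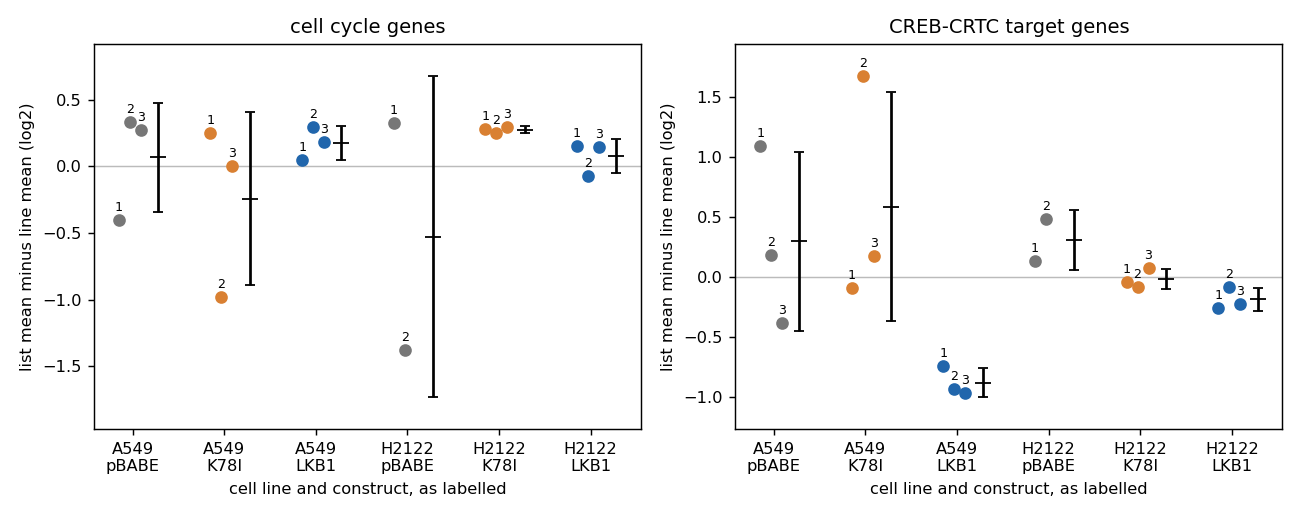
Mean of the cell cycle list (left) and of the CREB and CRTC target list (right) on each array, minus the mean of its cell line (log2), by labelled construct, with replicate numbers beside the points and group mean and SD as bars. A549 K78I replicate 2 lies lowest of its line for the cell cycle list (−0.98) and highest for the CREB and CRTC targets (1.67).

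Of 31 collagen, lysyl oxidase and matrix genes, 12 rose in A549 and 0 fell, including COL1A1, LOXL2 (3.10 ± 0.36, SE) and COL4A2 (1.97 ± 0.21, SE), although the median of the list was only 0.02 (camera adjusted p = 3.71e-05; adjusted p = 0.146 with an estimated correlation); 13 rose adjusted over the list alone. Of 25 mesenchymal genes, 7 rose, led by SPARC, the integrin subunit ITGB3 (1.92), TGFBI (0.99) and vimentin (VIM, 0.66) (camera adjusted p = 3.71e-05; adjusted p = 0.146 with an estimated correlation). Of 27 adhesion and polarity genes, 7 rose, among them the integrin subunits ITGB6 (3.06), ITGB4 (1.37) and ITGA3 (1.05) (camera adjusted p = 0.00573; adjusted p = 0.235 with an estimated correlation). Targets of YAP and TEAD had 7 of 25 higher, with CCN2 at 1.79 and TGFB2 at 1.78 (camera adjusted p = 0.00573; adjusted p = 0.474 with an estimated correlation). That call was lost without K78I replicate 1 (adjusted p = 0.0712) and against K78I alone (median 0.05, adjusted p = 0.223). The control array K78I replicate 2 had the highest mean of this list, at 0.61 above the line mean, over 0.26, 0.24 and 0.20 on the LKB1 arrays. Hypoxia and glycolysis genes had 6 of 28 higher, with the glucose transporter SLC2A1 at 1.16, KDM3A at 0.71 and BNIP3L at 0.79 (camera adjusted p = 0.000209; adjusted p = 0.255 with an estimated correlation). The epithelial list was not called (camera adjusted p = 0.0611), but 4 of its 26 members fell, the membrane protein MAL2 (−2.997), E-cadherin (CDH1, −1.17), the tight junction claudin CLDN1 (−0.81) and the splicing regulator ESRP2 (−0.49). Without LKB1 replicate 2 the adjusted p was 0.0677 for CDH1 and 0.135 for CLDN1. Adjusted over the list alone, the counts of higher and lower genes were 9 and 1 for mesenchymal genes, 8 and 0 for adhesion, 10 and 1 for YAP and TEAD targets, 11 and 1 for hypoxia and glycolysis, and 2 and 5 for epithelial genes.

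Signalling and metabolic lists were also tested in A549. Among 22 MAPK feedback genes, ETV4 (−0.89), the growth factor EREG (−2.67), SPRY4 (−0.81), SPRY1 (−0.71) and EGR1 (−2.42) fell, and the receptor EPHA4 rose by 1.14 (camera adjusted p = 0.000174; adjusted p = 0.292 with an estimated correlation). The mean of this list was highest in A549 on 2 controls with low cell cycle genes, K78I replicate 2 and pBABE replicate 1, at 0.96 and 0.59 above the line mean. Without the 3 such controls its median went from −0.57 to −0.22 (camera adjusted p = 0.00207). The amino acid transporter subunits SLC7A5 (−0.63) and SLC3A2 (−0.54), the transcription factor CEBPB (−1.39) and STC2 (−1.41) were the 4 of 29 ATF4 response genes that fell (camera adjusted p = 4.31e-06; adjusted p = 0.424 with an estimated correlation). K78I replicate 3, pBABE replicate 1 and K78I replicate 2 lay at 0.78, 0.69 and 0.45 above the line mean for this list. The other 3 controls, between −0.21 and −0.33, overlapped the LKB1 arrays. Without the 3 low cell cycle controls its median went from −0.535 to −0.34 (camera adjusted p = 0.000116). Oxidative phosphorylation genes had 3 of 29 lower, CYC1 (−0.56), NDUFA9 (−0.50) and the coactivator PPARGC1A (−3.30) (camera adjusted p = 0.0026; adjusted p = 0.292 with an estimated correlation). Interferon-stimulated genes had 5 of 34 higher, SAMD9 (1.69), PARP9 (1.09), the RNA sensor RIGI (0.54), IFIT1 (0.87) and IFIT3 (0.47) (camera adjusted p = 0.00251; adjusted p = 0.0761 with an estimated correlation). The p53 targets TP53I3 (1.78), TP53INP1 (1.47) and PHLDA3 (0.49) rose among 23 (camera adjusted p = 0.0242; adjusted p = 0.293 with an estimated correlation). Of 29 lysosome and autophagy genes, NPC2 (1.32), MITF (1.08), WIPI1 (0.97), LAMP2 (0.37) and ATP6V1H (0.32) rose (camera adjusted p = 0.0489; adjusted p = 0.437 with an estimated correlation), with a camera adjusted p of 0.0603 after median centring. Against K78I alone the camera adjusted p was 0.223 for p53 targets, 0.0639 for lysosome and autophagy and 0.0642 for oxidative phosphorylation. For p53 targets K78I replicate 2 lay at 0.30, over every LKB1 array (0.24, 0.03 and 0.09). Their call was lost without LKB1 replicate 1, pBABE replicate 2 or K78I replicate 3 (0.0897, 0.0675 and 0.0817). That of lysosome and autophagy was lost without LKB1 replicate 1 or 3, K78I replicate 1 or 2, pBABE replicate 2 or 3 or H2122 K78I replicate 1 (0.0503 to 0.144). It was lost too without the 2 arrays with STK11 at odds with their label (0.258), without every array whose labels or STK11 level disagree (0.261), with array weights (0.0651) and with the dimmest 30% of genes left out (0.106). That filter also ended the p53 call (0.0626). SPRY1, EGR1, IFIT3 and ATP6V1H were chosen after their values were seen. Without LKB1 replicate 1 the adjusted p was 0.0747 for CYC1, 0.113 for NDUFA9, 0.0847 for TP53INP1, 0.197 for PHLDA3, 0.147 for WIPI1 and 0.144 for LAMP2. Without LKB1 replicate 3 it was 0.173 for STC2, 0.116 for SPRY4, 0.0781 for PPARGC1A and 0.051 for EPHA4.

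The cell cycle list was called higher in A549 with 0 of 36 members called by limma, and 0 adjusted over the list alone (camera adjusted p = 0.0439; adjusted p = 0.884 with an estimated correlation). This call was lost without the 3 controls with low cell cycle genes, which were chosen by this same list, and the median went from 0.21 to −0.07 (camera adjusted p = 0.428). It was also lost without pBABE replicate 1, K78I replicate 2 or LKB1 replicate 2 or 3 alone (0.227, 0.503, 0.166 and 0.0774), without the 2 arrays with STK11 at odds with their label (0.298), with array weights (0.453) and with the dimmest 30% of genes left out (0.101). Small nucleolar and spliceosomal RNAs were called lower with 3 lower and 1 higher of 219 (camera adjusted p = 0.0439; adjusted p = 0.592 with an estimated correlation), and 1 and 1 adjusted over the list alone. That call was lost against K78I (camera adjusted p = 0.296) and without any 1 of 6 arrays, pBABE replicates 1 and 3, K78I replicates 1 and 3 and LKB1 replicates 2 and 3 (0.0726 to 0.165). Adjusted over the list alone, the counts of higher and lower genes were 1 and 10 for MAPK feedback, 1 and 9 for the ATF4 response, 0 and 5 for oxidative phosphorylation, 5 and 0 for interferon-stimulated genes, 7 and 0 for p53 targets and 8 and 0 for lysosome and autophagy. Camera called 16 of 30 lists in A549 with the preset correlation, 9 higher and 7 lower, and 0 with an estimated one, while the directional fry test called 12. It also called 12 lists between the A549 arrays labelled K78I and pBABE, where 0 lists were called with an estimated correlation or by fry and no gene passed in limma. The median of a list and its test differed in sign for squamous genes in A549 and for sterol synthesis, FOXO and PI3K response, neuroendocrine, fibroblast and housekeeping genes in H2122, none of them called in that line. The mean differed in sign from the median and the test for alveolar genes and for FOXO and PI3K response genes in A549.

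In H2122, fibronectin (FN1) rose from 7.22 ± 1.31 on 5 control arrays to 11.11 ± 0.11 on 3 LKB1 arrays (SD), by 3.89 ± 0.45 (SE, adjusted p = 8.44e-05). TMEM45A had the lowest p, with a rise of 3.37 ± 0.13 (SE, adjusted p = 2.51e-09). The activin antagonist follistatin (FST, 3.47), tenascin C (TNC, 3.40), TENM2 (3.25), LRRN1 (3.23), the metalloprotease ADAM19 (3.14) and IGFBP7 (3.13) completed the largest rises. Falls were smaller. They included the phosphodiesterase PDE3A (−2.55 ± 0.47, SE, adjusted p = 0.00322), CHRNA9 (−2.25), CPS1 (−2.10), TSPAN8 (−2.06), STC1 (−2.06), MUC15 (−1.92), PPP1R3C (−1.91) and MUCL1 (−1.88). Limma called 1308 genes, 896 higher and 412 lower, of which 347 and 63 changed at least 2-fold. The count was 789, 868 and 755 without LKB1 replicates 1, 2 and 3 and 422 without the 3 arrays whose labels disagree. With these arrays grouped by source name, which STK11 on pBABE replicate 2 and K78I replicate 3 goes against, the count was 1. It was 2345 without the 3 control arrays with low cell cycle genes, and without LKB1 replicate 1 the adjusted p was 0.0953 for CPS1, 0.116 for STC1 and 0.106 for MUC15.

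The antigen presentation list stood out in H2122, with 9 of 18 genes higher and 0 lower and a median difference of 0.41. It held the peptide transporter subunit TAP1 (0.72 ± 0.10, SE), tapasin (TAPBP, 0.75), HLA-F (0.85) and beta-2-microglobulin (B2M, 0.82), and was the 1 list in this comparison called by camera both with the preset correlation (adjusted p = 5.59e-08) and with an estimated one (adjusted p = 0.0045); 9 rose adjusted over the list alone. Of 27 NF-kB and cytokine genes, 7 rose, among them IL32 (1.80), the checkpoint ligand CD274 (1.62), IL1B (1.89) and CSF1 (1.09) (camera adjusted p = 8.17e-05; adjusted p = 0.209 with an estimated correlation). Interferon-stimulated genes had 6 higher and 1 lower of 34, with SAMD9 at 1.43 and IFI44 at 0.78 (camera adjusted p = 0.0384; adjusted p = 0.0944 with an estimated correlation). The interferon call was lost without pBABE replicate 1, LKB1 replicate 1 or 3 or K78I replicate 1 or 2 (0.0506 to 0.0973), and with the dimmest 30% of genes left out (0.071). Grouping by source name also ended the calls of the interferon, mesenchymal and YAP and TEAD lists (0.205 each) and of squamous genes (0.708). Mesenchymal genes had 8 higher and 1 lower of 25, with N-cadherin (CDH2) at 2.93 ± 0.19 (SE) and TGFBI at 1.53 (camera adjusted p = 5.65e-06; adjusted p = 0.0932 with an estimated correlation). Matrix genes had 8 of 31 higher, with the protease PLAU at 2.03, the basement membrane collagens COL4A2 at 1.94 and COL4A1 at 1.77, and MMP7 at 2.73 (camera adjusted p = 1.07e-06; adjusted p = 0.0617 with an estimated correlation). YAP and TEAD targets had 9 of 25 higher, with PTPN14 at 1.15, NT5E at 2.10 and the AMPK-related kinase NUAK2 at 1.92 (camera adjusted p = 1.27e-06; adjusted p = 0.217 with an estimated correlation). Adhesion genes had 8 of 27 higher, with ITGB6 at 2.54, ITGA2 at 1.43 and ITGA6 at 1.05 (camera adjusted p = 0.00447; adjusted p = 0.177 with an estimated correlation). Squamous lineage genes had 4 of 17 higher, 4 of them adjusted over the list alone, S100A2 (2.52), the keratin KRT5 (2.08), SERPINB13 (2.08) and DSG3 (1.07) (camera adjusted p = 0.000834; adjusted p = 0.327 with an estimated correlation). That call was lost with the dimmest 30% of genes left out (0.0589) and without every array whose labels or STK11 level disagree (0.0537). The control array K78I replicate 1 lay at 0.33 above the line mean for this list, over LKB1 replicate 2 at 0.02. Without H2122 LKB1 replicate 1 the adjusted p was 0.0562 for SAMD9, 0.06 for CSF1, 0.185 for SERPINB13 and 0.15 for DSG3. Adjusted over the list alone, the counts of higher and lower genes were 10 and 1 for NF-kB, 7 and 3 for interferon-stimulated, 9 and 1 for mesenchymal, 11 and 0 for matrix, 11 and 0 for YAP and TEAD, and 9 and 2 for adhesion genes.

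Ribosomal protein genes were lower in H2122, in 7 of 32 members, with RPL13 at −0.58 and RPS23 at −0.38 and a median of −0.22 (camera adjusted p = 2.8e-09; adjusted p = 0.0944 with an estimated correlation); 12 fell adjusted over the list alone. Oxidative phosphorylation genes had 5 of 29 lower, the respiratory chain subunits NDUFV2 (−0.47), NDUFS3 (−0.42), UQCRC2 (−0.28), CYC1 (−0.45) and COX5B (−0.30, chosen after its value was seen) (camera adjusted p = 1.27e-06; adjusted p = 0.0944 with an estimated correlation). The recalled tumour score had 4 of 14 lower, PDE4D (−1.09), CPS1, RFK (−0.62) and HAL (−1.27) (camera adjusted p = 2.05e-05, adjusted p = 0.327 with an estimated correlation). Grouping by source name ended this call (camera adjusted p = 0.862). ATF4 response genes had 1 higher and 1 lower of 29, the transporter SLC1A4 at 1.22 and the serine synthesis enzyme PSAT1 at −0.91 (camera adjusted p = 0.00367; adjusted p = 0.806 with an estimated correlation). The ATF4 call was lost without the 3 controls with low cell cycle genes, where the median went from −0.40 to −0.18 (camera adjusted p = 0.156); pBABE replicate 2, 1 of the 3, lay at 0.86 above the line mean. It was lost too without that array alone (0.299), without the 3 arrays whose labels disagree (0.271) and against K78I (0.19). The cell cycle list was called higher with 0 members called by limma, 0 adjusted over the list alone (camera adjusted p = 0.0386; adjusted p = 0.94 with an estimated correlation). Without pBABE replicate 2 alone the direction was lower (camera adjusted p = 0.0574), and the call was lost without LKB1 replicate 1 or 3 or K78I replicate 1 (0.0873, 0.117 and 0.0758), with pooled controls (0.222) and with the dimmest 30% of genes left out (0.0609). Without the 3 arrays whose labels disagree it was called lower (0.0436). Without the 3 controls, chosen by this same list, the median turned from 0.16 to −0.24 (camera adjusted p = 0.000105 for lower), and against K78I alone it was −0.22 (camera adjusted p = 0.187). CREB and CRTC targets were not called in H2122 (camera adjusted p = 0.0952): PDE4D fell by 1.09 and PDE4B by 0.88, while the activin subunit INHBA rose by 2.71 and the scaffold protein NEDD9 by 2.01. Epithelial genes went both ways, with P-cadherin (CDH3) at 1.47, MUC1 at −1.10, ELF3 at −0.64 and ESRP2 at −0.58. Without LKB1 replicate 2 the adjusted p was 0.109 for NDUFV2, 0.152 for UQCRC2, 0.193 for CYC1, 0.0863 for NDUFS3, 0.148 for RPS23, 0.195 for HAL, 0.232 for PSAT1, 0.133 for SLC1A4 and 0.155 for ELF3. Without LKB1 replicate 1 it was 0.0824 for RPL13 and 0.0696 for RFK. With a replicate block HAL, PSAT1, NDUFS3, UQCRC2 and CYC1 lost their call, and so did the cell cycle list (camera adjusted p = 0.0583). Adjusted over the list alone, 8 oxidative phosphorylation genes, 6 tumour score genes and 1 ATF4 response gene were lower. Camera called 13 of 30 lists with the preset correlation, 9 higher and 4 lower; fry called 10.

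**Figure D3:**
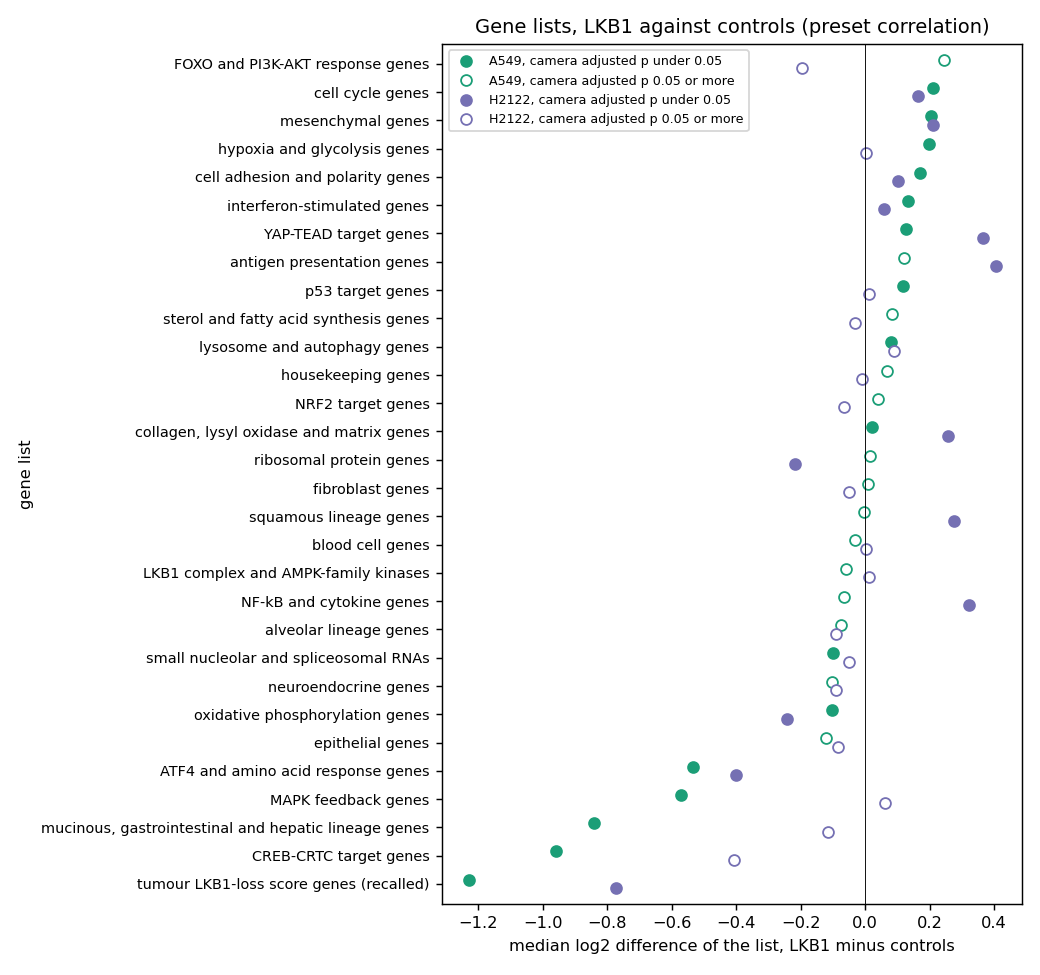
Median log2 difference between LKB1 and control arrays for each of the 30 gene lists in A549 and H2122; filled points passed camera with the preset correlation. The recalled tumour LKB1-loss score had the lowest median in both lines (−1.23 in A549 and −0.77 in H2122), and antigen presentation the highest in H2122 (0.41).

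Kinases downstream of LKB1 were examined as a list of 21 genes of the LKB1 complex and the AMPK family. NUAK1 rose in both lines, by 1.202 ± 0.19 in A549 (SE, adjusted p = 0.000882) and 2.20 ± 0.20 in H2122 (SE, adjusted p = 9.03e-06). SIK3 was lower in A549 (−0.85), and NUAK2 (1.92) and MARK1 (0.47) were higher in H2122, the latter with an adjusted p of 0.0645 without LKB1 replicate 3. The list as a whole was called in neither line (camera adjusted p = 0.96 in A549 and 0.143 in H2122). Without the 3 controls with low cell cycle genes it was called higher for the mean of both lines (camera adjusted p = 0.0423), with 4 members higher and 2 lower. The control array A549 K78I replicate 2 lay at 0.40 above the line mean for this kinase list, over every LKB1 array of A549. Targets of NRF2 were also called in neither line (camera adjusted p = 0.833 and 0.317), with 0 of 30 members called by limma in each. Without the 3 controls with low cell cycle genes 1 member was higher and 4 lower in A549, 0 higher and 4 lower in H2122, and the list was called lower for the mean (adjusted p = 0.0423). K78I replicate 2 lay at −0.65 against the A549 mean for this list, apart from the other arrays. Without those controls p53 targets and lysosome and autophagy genes were also called higher in H2122 (0.0352 and 0.00132). Of 18 markers of blood cells 0 were called by limma in A549 and 2 in H2122, LCP1 (2.90) and PECAM1 (−0.79, adjusted p = 0.0838 without LKB1 replicate 3).

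Wild-type LKB1 was then set against each control alone. The K78I control is meant to separate kinase activity from the presence of the protein, which was not measured here. In A549 it can do so only in part, since K78I replicate 2 had STK11 at 7.14, beside 6.88 and 7.38 on 2 pBABE arrays. Against K78I, A549 showed SPARC higher by 6.22 ± 0.22, SLC2A12 by 3.24 ± 0.28 and CPS1 lower by 5.36 ± 0.53 (SE). H2122 showed TMEM45A higher by 3.26 ± 0.15, CDH2 by 2.43 ± 0.22 and FN1 by 2.999 ± 0.50 (SE). Limma called 943 genes in A549, 639 higher and 304 lower (494 and 396 after median centring), and 698 in H2122, 535 higher and 163 lower. Against pBABE, SPARC was higher by 6.09 ± 0.22 in A549 (SE), FN1 by 4.79 ± 0.56 in H2122 and CDH2 by 3.43 ± 0.24 in H2122. There limma called 987 genes in A549, 678 higher and 309 lower, and 1037 in H2122, 749 higher and 288 lower (628 and 465 after median centring). The H2122 counts against K78I were 402, 423 and 350 without LKB1 replicates 1, 2 and 3 and 401 and 281 without K78I replicates 2 and 3; against pBABE they were 1800 without pBABE replicate 1, 462 without pBABE replicate 2 and 639 without LKB1 replicate 3. In A549 they were 585 and 421 without LKB1 replicates 1 and 3, 1625 without K78I replicate 1 and 568 without K78I replicate 2 against K78I. Against pBABE they were 608 and 524 without LKB1 replicates 1 and 3, 560 and 505 without pBABE replicates 1 and 2, and 1520 without K78I replicate 2.

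Kinase-dead LKB1 was compared with the empty vector to see what the protein does without kinase activity, and no gene passed in either line. In A549, SPARC differed by −0.13 ± 0.22 and IGFBP7 by −0.30 ± 0.30 between the arrays labelled K78I and pBABE (SE); in H2122, IGFBP7 differed by 1.19 ± 0.34, CDH2 by 1.00 ± 0.24 and FN1 by 1.79 ± 0.56 (SE, adjusted p = 0.486, 0.341 and 0.54). STK11 differed by 5.00 ± 0.94 in H2122 (SE, adjusted p = 0.167), and by 5.00 ± 0.11 with an adjusted p of 1.61e-07 when H2122 was fitted alone, without the spread of the A549 arrays. Limma called 0 genes in A549, with 472 at an unadjusted p under 0.05 where chance gives 898, and 0 in H2122, with 1260 at that level. The A549 comparison contains both arrays whose STK11 goes against the label; without them it called 35 genes, 9 higher and 26 lower, including STK11 at 3.35 ± 0.22 (SE, adjusted p = 1.5e-05). It called 2 genes without pBABE replicate 3. The H2122 comparison rests on 2 pBABE arrays and called 1041 genes without pBABE replicate 1, where the lone pBABE array is assumed to vary like the other groups.

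The mean effect over the lines was tested next. IGFBP7 rose by 3.50 ± 0.19 on average over the lines (SE, adjusted p = 4.85e-08), the sugar transporter SLC2A12 by 3.03 ± 0.17 (adjusted p = 5.99e-08), ADAM19 by 3.01 ± 0.27, the tetraspanin TSPAN2 by 2.89 ± 0.17, ITGB6 by 2.80 ± 0.29 and MMP7 by 2.67 ± 0.33 (SE). CPS1 fell by 3.73 ± 0.33 (SE, adjusted p = 5.65e-06), PDE3A by 2.83 ± 0.33 and CSGALNACT1 by 1.92. These 9 genes were also called in each line. MUC5B, SLPI, SMOC1, S100P and MUC13 passed for the mean (−2.85, −2.37, −2.29, −2.11 and −2.10) but were not called in H2122, and SMOC1 was called in neither line. PIK3IP1, IRS1, SESN3 and the p53 target FAS passed for the mean (1.12, 1.09, 0.88 and 0.49) but were not called in A549. The FOXO and PI3K response list, which holds the first 3 of these, was not called for the mean (median −0.05, camera adjusted p = 0.529), with 7 higher and 1 lower of 27. Limma called 2437 genes for the mean effect, 1482 higher and 955 lower; after median centring 1213 were higher and 1483 lower. Camera called 18 of 30 lists for the mean with the preset correlation, and with an estimated correlation 4 of them, the matrix, antigen presentation and interferon-stimulated lists (adjusted p = 0.0237 each) and the mesenchymal list (adjusted p = 0.0255). As written, the antigen presentation and interferon-stimulated lists share TAP1, PSMB8 and PSMB9, so they are not independent. The mesenchymal list shares TGFB2 and AXL with the YAP and TEAD targets. Without the 3 controls with low cell cycle genes the MAPK feedback call for the mean was lost (camera adjusted p = 0.588) and the cell cycle list turned from higher to lower (median 0.21 to −0.15, camera adjusted p = 0.00293). The lines had 261 genes called higher in both, where independent lists would share 49.1, and 63 called lower in both, where 12.2 would be shared; 28 were called in opposite directions. Across all 17958 genes, which are not independent replicates, the effects in the lines correlated with Pearson's r = 0.352 and Spearman's rho = 0.29, and 60.2% had the same sign.

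**Figure D4:**
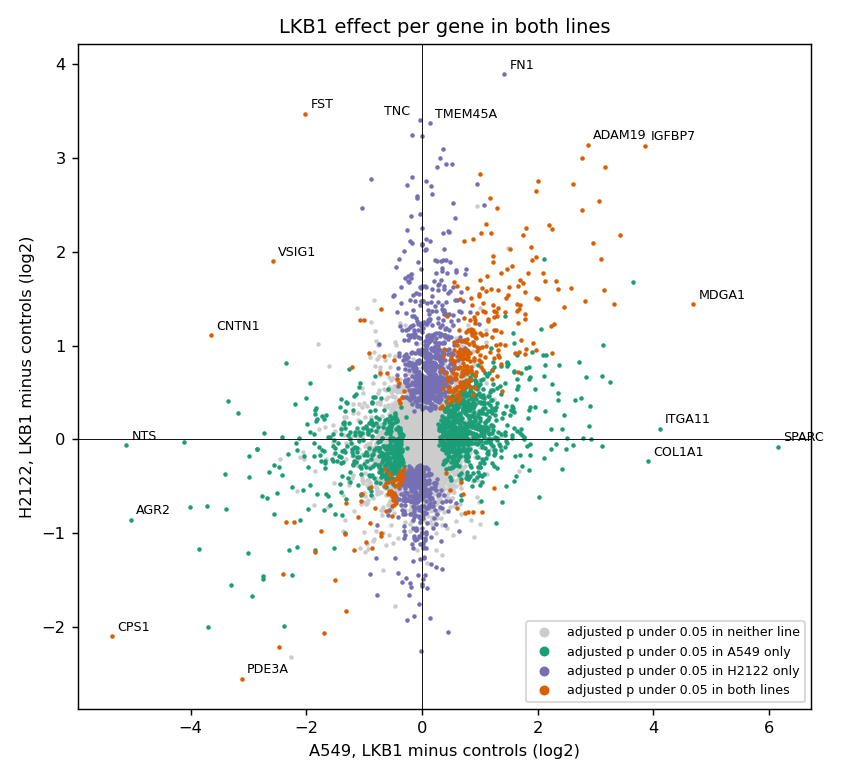
LKB1 minus control difference (log2) of every gene in A549 (horizontal) and H2122 (vertical), coloured by the line or lines in which limma's adjusted p was under 0.05. IGFBP7 and ADAM19 rose in both, CPS1 and PDE3A fell in both, SPARC (6.15 in A549 and −0.08 in H2122) moved in A549, and FST, CNTN1 and VSIG1 moved in opposite directions.

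Other genes answered LKB1 differently in the lines. SPARC differed most, with an H2122 minus A549 effect of −6.23 ± 0.28 (SE, adjusted p = 1.26e-08); in H2122 its level was 3.88 with LKB1 and 3.96 in controls. Among effects lower in H2122, COL1A1 (−4.14), ITGA11 (−4.00), MDGA1 (−3.25) and the cadherin FAT3 (−3.17) came next. Follistatin (FST) fell by 2.02 in A549 and rose by 3.47 in H2122, a difference of 5.49 ± 0.67 (SE, adjusted p = 0.00046). The adhesion molecule CNTN1 fell by 3.66 in A549 and rose by 1.11 in H2122, and VSIG1 fell by 2.58 and rose by 1.90. NTS and AGR2 had differences of 5.05 and 4.18. Limma called 647 genes for the difference between lines, 355 with the higher effect in H2122 and 292 with the higher effect in A549. The count was 421 and 310 without A549 LKB1 replicates 2 and 3, and 381, 427 and 340 without H2122 LKB1 replicates 1, 2 and 3. Camera called 9 of 30 lists for the difference, 0 with an estimated correlation (smallest adjusted p = 0.118) and fry 3. The H2122 effect was higher for NF-kB and cytokine genes (median difference 0.55, camera adjusted p = 2.3e-06; adjusted p = 0.257 with an estimated correlation) and CREB and CRTC targets (0.84, camera adjusted p = 8.25e-06; adjusted p = 0.619 with an estimated correlation), and lower for ribosomal protein genes (−0.25, camera adjusted p = 7.78e-08; adjusted p = 0.257 with an estimated correlation). Without the 3 controls with low cell cycle genes these medians were 0.55, 0.35 and −0.19.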

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

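The tests of exchanged labels, of transgene loss, of control-cell growth on the 3 gene lists, of fibroblasts and of wild-type LKB1 cells only were chosen only after the result was seen, and so were the alternatives that leave out arrays with unexpected STK11 or with low cell cycle genes.

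The first pattern weighed was STK11 on the arrays labelled A549 pBABE replicate 3 and K78I replicate 2. These arrays had the level of the other label, at 10.52 against 10.42 to 10.54 and at 7.14 against 6.88 to 7.38, which raised the question of an exchange of labels and cannot answer it. Over the other genes, as deviations from the mean of the 6 controls, 2 of the 2 arrays had a higher mean correlation with the other label's remaining arrays than with their own. For pBABE replicate 3 it was 0.282 against −0.223, and for K78I replicate 2 −0.0538 against −0.498. Single correlations overlapped, from 0.125 to 0.439 against −0.704 to 0.258 and from −0.55 to 0.442 against −0.646 to −0.349. The value of 0.442 was with pBABE replicate 1, which shares low cell cycle genes. The test first asked only for higher mean correlations, which 2 of the 2 arrays had. After its values were seen it was made to ask also that no single correlation go against an exchange. That was not met, so an exchange stays open. Loss of the transgene in K78I replicate 2 as the whole cause is argued against by pBABE replicate 3, which lay 3.13 above the higher of the other pBABE arrays. That the array labelled pBABE replicate 3 holds wild-type LKB1 cells only is argued against by the genes called without it, 1686 in number. Its median position between the control mean at 0 and the LKB1 mean at 1 was 0.333 (quartiles 0.147 and 0.525), and K78I replicates 1 and 3 lay at 0.318 and 0.267. The 3 LKB1 arrays, each placed in the same way, had medians of 0.853, 0.864 and 1, and the lowest of their first quartiles was 0.581. SPARC on this array was 4.61, where the lowest LKB1 array had 9.75. STK11 on this array, at 10.52, lay above the 3 LKB1 arrays, at 9.42, 10.23 and 9.62. That argues against a smaller share of such cells among empty-vector cells as the cause of its STK11 level. Whether some such cells were present stays open. The third quartile of this array, 0.525, did not fall below the bound of 0.5 set beforehand. That of the control K78I replicate 1 was 0.562, so the bound cannot tell an array with such cells from another control. No biological explanation was tested, and no array was regrouped.

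The second pattern was the lower CREB and CRTC target, recalled tumour score and mucinous lists in A549 with LKB1. Slower growth of the control cells on the 3 arrays with low cell cycle genes could account for part of it. As the whole cause it is argued against for the tumour score, which kept a share of 0.773 of its median difference without these arrays, and for the mucinous list, which kept 0.843 (camera adjusted p = 6.74e-09 and 3.58e-06 with the preset correlation). With an estimated correlation and all arrays neither was called (adjusted p = 0.204 each), nor were CREB and CRTC targets (0.279), so the shares and not these p-values carry the argument. CREB and CRTC targets kept 0.433, going from −0.96 to −0.42 (camera adjusted p = 6.74e-09). For this list growth state cannot be told apart from a response to LKB1, because the share lay between the bounds of the test. A response to LKB1, the difference the groups were designed to show, stays open for all 3 lists, and other technical causes were not tested.

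The third pattern was higher SPARC, COL1A1 and ITGA11 in A549 with LKB1. Fibroblasts in the LKB1 cultures are argued against, because other abundant fibroblast transcripts did not rise with them. Of 4 such transcripts LUM had the highest difference at 0.162, with COL1A2 at 0.04, COL3A1 at 0.02 and DCN at −0.09. The fibroblast list was not called in A549 (camera adjusted p = 0.155, fry adjusted p = 0.06; fry's unadjusted value was 0.03), with 3 of 16 genes higher and 0 lower. These were COL1A1, PDGFRA (0.782, the highest of the other 15 genes, whose median was −0.003) and FBLN1 (0.57). Without LKB1 replicate 1 the adjusted p was 0.186 for PDGFRA and 0.101 for FBLN1, without LKB1 replicate 3 it was 0.157 and 0.11, and without pBABE replicate 1 it was 0.0632 for PDGFRA. Slower growth of the control cells is argued against as the whole cause, since the smallest share of a difference kept without the 3 arrays was 0.893. A response to LKB1 may then be a biological hypothesis, found and tested on the same data; other technical causes were not tested.

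Other splits of the same arrays were counted with the controls of a line pooled. In A549, 2 of 84 splits called as many genes as the real one (1625), a share under 0.05 that argues against chance. The highest other split called 2110, more than the real one, so chance is not excluded. That split set pBABE replicate 1, K78I replicate 2 and K78I replicate 3 against the rest, which points to a structure among the A549 controls. In H2122, 1 of 56 splits, the real one, called as many (1278, highest other 75), which argues against chance. For genes shared in direction with A549 it was again 1 of 56 (318, highest other 1). No other split called more than 75 genes, so none could share 318, and this count adds nothing to the first. For the mean of both lines 1 of 100 splits called as many (2526, highest other 451), which argues against chance there too. For the difference between lines 1 of 100 splits called as many, and the highest other came close (623 and 603). These splits regrouped the arrays of both lines, which breaks up the LKB1 effect itself and not only its difference between lines. They cannot tell whether that difference is due to chance.

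For gene lists in A549, 3 of 84 splits called as many as the real one (15, highest other 16). That share lies under 0.05 and argues against chance. A split other than the real one called more lists, so chance is not excluded. Nor was it excluded in H2122, with 9 of 56 (13, highest other 14), or for the difference between lines, with 53 of 100 (9, highest other 20). Comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05. The real split gave 943 genes for A549 LKB1 against K78I (1 split as large, highest other 1), 987 against pBABE (1 split, highest other 0) and 698 for H2122 LKB1 against K78I (1 split, highest other 0). For A549 K78I against pBABE limma called 0 genes in the real split, 472 at an unadjusted p under 0.05. With a count of 0 all 10 splits are as large by construction, so this comparison says nothing about chance. The highest other split called 961 genes and set the same pBABE replicate 1, K78I replicate 2 and K78I replicate 3 apart.

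The LKB1 effect differed between the lines by the interaction test for 647 genes. The effect was higher in H2122 than in A549, as log2 H2122 minus A549, for FST (5.49), NTS (5.05), CNTN1 (4.77), VSIG1 (4.48), AGR2 (4.18), GABRA2 (4.08), TNC (3.43), TENM2 (3.42), CPS1 (3.27), LRRN1 (3.23), TMEM45A (3.23), INSL4 (3.005) and INHBA (2.975). It was also higher for MAL2 (2.82), VTN (2.75), LCP1 (2.64), CDH2 (2.51), FN1 (2.47), NUAK2 (2.32), NEDD9 (2.32), NT5E (2.26), KRT5 (2.08), S100A2 (1.985), CD274 (1.98), IL1B (1.96), CDH1 (1.63), CLDN1 (1.49), PDE4B (1.34), CDH3 (1.19), ITGA6 (0.89) and TAP1 (0.62). It was lower in H2122 for SPARC (−6.23), COL1A1 (−4.14), ITGA11 (−4.00), MDGA1 (−3.25), FAT3 (−3.17), CHRNA9 (−2.24), PPP1R3C (−2.045), NIPAL4 (−1.89), MUCL1 (−1.73), MUC1 (−1.12), SLC2A1 (−0.92), PARP9 (−0.90) and RPL13 (−0.69).

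By camera with the preset correlation the median effect was higher in H2122 for mucinous and hepatic lineage genes (0.90), CREB and CRTC targets (0.84), the recalled tumour score (0.66), MAPK feedback (0.58), NF-kB and cytokine genes (0.55), squamous genes (0.35) and antigen presentation (0.32). It was lower for hypoxia and glycolysis genes (−0.36) and ribosomal protein genes (−0.25). With an estimated correlation 0 of these lists were called (smallest adjusted p = 0.118), and fry called 3. Without the 3 controls with low cell cycle genes 3 of the 9 calls were lost, for the recalled tumour score (0.435, camera adjusted p = 0.103), squamous genes (0.09, adjusted p = 0.171) and hypoxia and glycolysis genes (−0.235, adjusted p = 0.0849). The difference for CREB and CRTC targets went to 0.35 and that for mucinous and hepatic lineage genes to 0.50, both still called. Leaving out 1 array ended the call of the tumour score for A549 pBABE replicate 1, K78I replicate 2 and LKB1 replicate 2 and for H2122 pBABE replicate 1, K78I replicates 1 and 2 and LKB1 replicate 2 (adjusted p from 0.0504 to 0.246). It ended that of hypoxia and glycolysis for A549 LKB1 replicates 1 and 3 and H2122 LKB1 replicate 1 (0.0589, 0.056 and 0.0704), and that of squamous genes for H2122 LKB1 replicate 1 (0.0589). Without the 3 H2122 arrays with conflicting labels the hypoxia and squamous calls were lost (0.0656 and 0.0712), and with array weights that of the tumour score (0.15). Grouping H2122 by source name ended the calls of antigen presentation, squamous and ribosomal protein genes (0.612, 0.895 and 0.0562).

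Signal also appeared in probe sets outside the gene comparisons. Of 12061 probe sets not listed in the annotation, 187 were called for A549 LKB1 against controls, 110 higher and 77 lower, and 137 for H2122, 103 higher and 34 lower. Of 2055 probe sets with several gene symbols, 94 and 81 were called.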

How the results depend on the processing

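The alternatives that leave out the 2 A549 arrays with STK11 at odds with their label, these and the 3 H2122 arrays with conflicting labels, or the 3 controls with low cell cycle genes were chosen only after the data had been seen. Where no cause is given below, the cause was not tested.

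Grouping H2122 by source name counts pBABE replicate 2, with STK11 at 6.22, as LKB1 and K78I replicate 3, at 11.26, as pBABE. STK11 on these arrays goes with the title and against this grouping. It gave 1 gene for LKB1 against controls, 0 against K78I and 2 against pBABE, 874 for the mean and 175 for the difference between lines; A549 gave 538 against K78I and 633 against pBABE. STK11 in H2122 reversed to −0.45 (adjusted p = 0.941), MUC15 to 0.23, HAL to 0.0832, IFI44 to −0.0562, IRS1 to −0.21, SERPINB13 to −0.14 and PECAM1 to 0.0692, and 167 of 294 named-gene results lost their call. In H2122 the mesenchymal, YAP and TEAD and interferon lists (adjusted p = 0.205 each), the tumour score (0.862) and squamous genes (0.708) lost theirs. The cell cycle list turned lower (2.78e-13), and ATF4 response genes turned higher without a call (0.133). For the difference between lines antigen presentation (0.612), squamous (0.895) and ribosomal protein genes (0.0562) lost their call. Without the 3 arrays, which leaves fewer samples, the H2122 counts were 422 against controls, 200 against K78I and 214 against pBABE, with 1486 for the mean and 209 for the difference, and 78 named-gene results lost their call.

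Array weights gave 3844, 1930 and 3829 genes in A549 for LKB1 against controls, K78I and pBABE, 2264, 3721 and 645 in H2122, 4250 for the mean and 1706 for the difference, and STK11 in H2122 at 2.48 (adjusted p = 0.0083). A fit per line gave 875, 407 and 548 in A549, 1 gene for H2122 K78I against pBABE, and STK11 in H2122 at 2.49 (adjusted p = 1.12e-05).

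Without the 2 A549 arrays, A549 LKB1 against pBABE gave 1803 genes, K78I against pBABE 35 in A549 and 1 in H2122, and STK11 was 0.95 in A549 (adjusted p = 0.00215) and 2.49 in H2122 (adjusted p = 1.63e-06). Without all 5 arrays the A549 counts were 579 against K78I, 1712 against pBABE and 25 for K78I against pBABE, and the H2122 counts 770, 320, 425 and 1, with STK11 at 0.95 (adjusted p = 0.00898) and 2.465 (adjusted p = 0.000366). Without the 3 controls with low cell cycle genes H2122 gave 2345 genes against controls and 1806 against K78I, with STK11 at 2.46 (adjusted p = 0.0102).

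An estimated correlation left 0 lists in A549, 1 in H2122 and 0 in the difference between lines; fry left 3 in the last. No label says that replicate numbers pair the arrays. Correlations across genes of deviations from the group mean, between same-numbered arrays of different groups, ran from −0.644 to 0.352 in A549 (4 of 9 over 0.1) and from 0.0639 to 0.42 in H2122 (6 of 7 over 0.1). Differently numbered arrays had mean r of 0.0178 and −0.131. In neither line did every array correlate best with one of its own number, but in H2122 the only exceptions were LKB1 replicate 3 and K78I replicate 3. A replicate block gave 1448 genes in A549 and 1255 in H2122 for LKB1 against controls, and 15 of 294 named-gene results lost their call, among them STC2 and CLDN1 in A549 and HAL, PSAT1, NDUFS3, UQCRC2 and CYC1 in H2122 (adjusted p from 0.0546 to 0.0967). The cell cycle list in H2122 lost its call too (adjusted p = 0.0583).

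Leaving out 1 array at a time gave ranges of 715 to 1924 for A549 LKB1 against controls (844 without LKB1 replicate 1, 715 without replicate 3), 421 to 1625 against K78I (585 and 421 without LKB1 replicates 1 and 3, 1625 and 568 without K78I replicates 1 and 2) and 505 to 1520 against pBABE (560 and 505 without pBABE replicates 1 and 2, 608 and 524 without LKB1 replicates 1 and 3, 1520 without K78I replicate 2). A549 K78I against pBABE ranged from 0 to 2 (2 without pBABE replicate 3). H2122 ranged from 755 to 1712 against controls (789, 868 and 755 without LKB1 replicates 1, 2 and 3), 281 to 1023 against K78I (402, 423 and 350 without LKB1 replicates 1, 2 and 3, 401 and 281 without K78I replicates 2 and 3) and 462 to 1800 against pBABE (1800 and 462 without pBABE replicates 1 and 2, 639 without LKB1 replicate 3). H2122 K78I against pBABE ranged from 0 to 1041 (1041 without pBABE replicate 1). The mean ranged from 1711 to 2759 and the difference between lines from 310 to 870 (421 and 310 without A549 LKB1 replicates 2 and 3, 381, 427 and 340 without H2122 LKB1 replicates 1, 2 and 3). STK11 ranged from 0.39 to 1.51 in A549 and from 2.45 to 2.525 in H2122, the lists from 13 to 16, 11 to 15 and 7 to 12. Of 294 named-gene results, 70 lost the call without some single array and 0 reversed. Where a group is left with 1 array, that array is assumed to vary like the other groups.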

Other observations

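Only the settings without the 2 A549 arrays with STK11 at odds with their label, without these and the 3 H2122 arrays with conflicting labels, and without the 3 control arrays with low cell cycle genes were chosen only after the result was seen.

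Every LKB1 array lay above every control array of its line for 1519 genes in A549 and 1534 in H2122, and below for 1195 and 1583. That is 15.1% of genes in A549 and 17.4% in H2122, where chance gives 2.38% and 3.57%.

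Called genes of both lines were shared in direction beyond what independent calls give under each alternative in which this was computed. Without the 3 H2122 arrays whose labels disagree, 111 were higher in both lines where 15.9 would be shared and 13 were lower where 1.74 would be. Without the 3 control arrays with low cell cycle genes, 408 were higher where 87.3 would be shared and 136 lower where 37.7 would be.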
